A study of Homo sapiens and Mus musculus with 13 samples.

How the data were processed

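Total RNA was extracted with RNeasy micro columns, and libraries were made with the Swift rapid RNA kit (human) or NEBNext Ultra II (mouse), per the labels' protocols. The submitters' processing notes name STAR 2.6.1, RSEM and DESeq2 and the builds hg19 and mm9, without saying which step or species each served. The aligner's settings, the annotation release and any use of strand are not given in the sources used here. Each human sample has an RSEM gene table, and the authors deposited expected counts, TPM and FPKM per gene cluster in it, per the file headers. RSEM's expected counts are estimates that need not be whole. TPM and FPKM were not used here. Each mouse sample has a deposited signal value per Ensembl gene, read counts that the authors divided by a DESeq2 size factor per library, as the labels and the values show.

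Groups came from the sample titles, and file names were not used for grouping. Human file names pair the libraries with other conditions than the labels do, and the mouse clone numbers in the files differ from those in the titles within the knock-in group. Clones are named here by title. The series design text calls the human libraries biological duplicates, and the mouse clones are separate single-cell clones. No label says that the 2 parental libraries came from separate cultures, so the spread between them may be technical. Replicates of each group differed by more than counting noise (chi-square over degrees of freedom of 11.3 to 32.1 in the human groups, 25.5 between the parental libraries and 6.11 to 11.4 between clones), which separate preparations from a shared culture would do as well, so this does not show that they are separate cultures. Every library was counted as a replicate, following the series design text for the human groups and without such a statement for the parental pair.

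Human expected counts were rounded to whole numbers. All 8 libraries entered a single edgeR fit with 4 groups (edgeR 4.0.16 in R 4.3.3, filterByExpr, TMM, robust quasi-likelihood), and 13590 of 31848 clusters were tested. The common biological coefficient of variation was 0.136. A human SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. The cluster numbers belong to UCSC transcript clusters, and only 6 of the 31848 matched a gene symbol through the reference tables. The planned human gene lists, named human genes and tests of the labels were therefore not analysed here, and the text gives 2 clusters that rose and 2 that fell, the largest changes with labelled dTag-13 among clusters with a mean of at least 5 CPM and non-overlapping libraries. No coordinates are given, since the reference at hand is of another build.

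Whole reads could be recovered from the mouse values: 100% of the values above 0 were whole multiples of their library's smallest value, within a tolerance of 0.01. Since the files hold normalized values, limma 3.58.1 with a trend and robust moderation on log2(value + 1) was the main test, as planned for that case, for the 13132 of 37991 genes with a mean of at least 10. This minimum was set after the unit was known. Fold changes on this scale understate the change of genes with few reads. Mouse symbols were those of the files, and 823 genes had none. Gene lists were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, and again with an estimated correlation. Under the filter at 50 the MHC class II, megakaryocyte and B cell lists kept fewer than 5 members, and their values there were not read. Ebf1 and Sox4 each have 2 identifiers, which count as 2 members. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison or over the lists. Where a group had no read, a fold is a bound from 3 counts over the group, and with 1 to 3 counts the ratio is given with an exact interval. These intervals and floors cover counting error only.

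Gene lists, tests, groups and alternatives were fixed before the data were examined. Named genes were those the design is about, the 6 largest rises and the 6 largest falls among called genes with at least 5 CPM and non-overlapping groups, and up to 4 members with the smallest p of each HOX list and of each list past the camera test. Chosen after their values were seen were Meis1, Hoxb4, Slc2a3, Hk1, Mcm3, Cpa3, Hdc, Cdkn1a, Mdm2, Mpo and the untested mast cell genes in the report and the genes named among the other observations. The 16 pathway lists cover the HOXA and HOXB clusters, HOX cofactors, monocyte and granulocyte maturation, MHC class II, MYC and ribosome biogenesis, p53, cell cycle, DNA replication, interferon, cholesterol, amino acid and unfolded protein stress, glycolysis, immediate early and nuclear transport genes. The 7 lists of cell types are erythroid, megakaryocyte, mast cell with basophil and eosinophil, B cell, T and NK cell, dendritic, and stromal with endothelial.

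The tests were run on simulated data with 200 changed genes at the real depths. For the labelled dTag-13 comparison, 14.3%, 89.0% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 11 false calls among 155 over 13373 genes. For the mouse comparison limma recovered 16.4%, 93.3% and 100% at the same sizes, with 4 false calls among 148 over 13148 genes. Simulated changes near 0.5 were thus mostly missed. The simulation gave every gene the same dispersion and changed only 200, whereas 5466 human clusters and 2101 mouse genes were called in the data. With more changed genes the adjusted threshold is less strict, so these shares do not measure the sensitivity of the reported tests. Alternatives were another normalization, no filter, DESeq2 1.42.0, a replicate block, fits of single comparisons, other pseudocounts and each library left out. Added after the data were seen were a mouse filter at 50, edgeR with TMM on recovered reads, thinning of parental replicate 2, the bounds without single libraries, the count of members in which the parental libraries differ and a reading of the fit without it. Figures were drawn with matplotlib 3.10.9.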

Results

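Gene expression was measured by RNA sequencing in a human acute myeloid leukaemia line and in a mouse haematopoietic progenitor line. OCI-AML3 is an established human line that carries NPM1c, the mutant nucleophosmin that accumulates in the cytoplasm, together with mutations in DNMT3A and NRAS per its labels. Its derivative called degron2 carries a degradable NPM1c, which dTag-13 directs to the proteasome through an FKBP-type tag. Selinexor (KPT-330) inhibits XPO1, the nuclear export receptor that NPM1c uses. The labels give 2 libraries to each of 4 human groups: OCI-AML3 with DMSO or with 25 nM Selinexor, and degron2 with DMSO or with 500 nM dTag-13, each for 24 h. The mouse cells are progenitors immortalized by HOXB8 and grown with stem cell factor and beta-estradiol. They comprise 3 single-cell clones with an NPM1c knock-in, labelled 12, 18 and 4, and 2 libraries of the parental line. Human counts were 9743235 and 9816226 (labelled degron2 DMSO), 17078147 and 17208192 (dTag-13), 14210727 and 16320226 (OCI-AML3 DMSO) and 12277424 and 16456947 (Selinexor). Median fragment lengths in the same order were 207.2 and 214.9, 266.4 and 234.9, 237.8 and 225.6, and 283.1 and 244.1 nt. Fragments were thus longer with labelled dTag-13 and Selinexor than with DMSO in the same labelled line. Effects of fragment length and depth on the human calls were not tested. The mouse values corresponded to 12235174, 9427149 and 7358340 reads in clones 12, 18 and 4, to 9728260 in parental replicate 1 and to 99557475 in parental replicate 2.

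The human files are attached to sample records whose labels differ from the names the files carry. The files of the records labelled OCI-AML3 DMSO are named for the degron line with DMSO, and those labelled degron2 DMSO for the degron line with dTag. The files of the records labelled Selinexor are named for OCI-AML3 with DMSO, and those labelled dTag-13 for OCI-AML3 with KPT. Groups follow the labels throughout, and "labelled" marks every human direction. NPM1, XPO1 and FKBP1A, which would check the labels, could not be looked up, because the human files give numbered clusters of UCSC transcripts and the reference used here does not pair those with gene names. The clusters are therefore given by number, and no gene list was tested in the human cells.

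If the labels hold, the comparison of degron2 cells labelled dTag-13 with those labelled DMSO asks what changes when NPM1c is degraded. Cluster 2745 had no count in the libraries labelled degron2 DMSO and 62.28 ± 9.70 CPM (SD, n = 2) in those labelled dTag-13, at least 427-fold higher against a floor of 3 counts over the group (217-fold and 209-fold without replicate 1 or 2 labelled degron2 DMSO). Cluster 31197 likewise went from no count to 46.15 ± 10.3 CPM (SD, n = 2), at least 316-fold higher (161-fold and 155-fold without these replicates). Cluster 28722 had 15.43 ± 3.16 CPM in the libraries labelled degron2 DMSO and a single count in those labelled dTag-13, a ratio of 521 with a 95% counting interval of 92.8 to 20600. Cluster 4034 was 265 times lower (90.1 to 1290), from 23.60 ± 0.661 CPM to 3 counts. By edgeR's quasi-likelihood test, 5466 of 13590 clusters changed (adjusted p under 0.05), 2769 of them higher and 2697 lower in the libraries labelled dTag-13. With library totals as the only scaling the split turned to 2290 higher and 3197 lower. At least 2-fold changes numbered 1428 upward and 1028 downward, and at least 16-fold changes 283 and 57. Under the file names this comparison sets OCI-AML3 with KPT against the degron line with dTag. Without replicate 1 labelled degron2 DMSO the count was 3576.

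If the labels hold, the comparison of OCI-AML3 cells labelled Selinexor with those labelled DMSO asks what changes when XPO1 is inhibited. The same 4 clusters moved the same way: cluster 31197 was at least 208-fold higher in the libraries labelled Selinexor (112-fold and 95.9-fold without replicate 1 or 2 labelled OCI-AML3 DMSO), cluster 2745 went from 3 counts to 49.72 ± 6.64 CPM (ratio 510, 95% counting interval 174 to 2470), cluster 4034 was 687 times lower (123 to 27200), and cluster 28722 fell from 9.10 ± 0.981 to 0.4459 ± 0.0679 CPM (adjusted p = 3.08e-06, edgeR). In all, 3756 clusters changed, 2040 higher and 1716 lower, with 241 and 42 past 16-fold. With library totals as the only scaling the split turned to 1653 higher and 2034 lower. Under the file names this comparison sets OCI-AML3 with DMSO against the degron line with DMSO. The count fell to 2332 and 2105 without replicate 1 or 2 labelled OCI-AML3 DMSO, and to 2415 without replicate 2 labelled Selinexor.

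**Figure D1:**
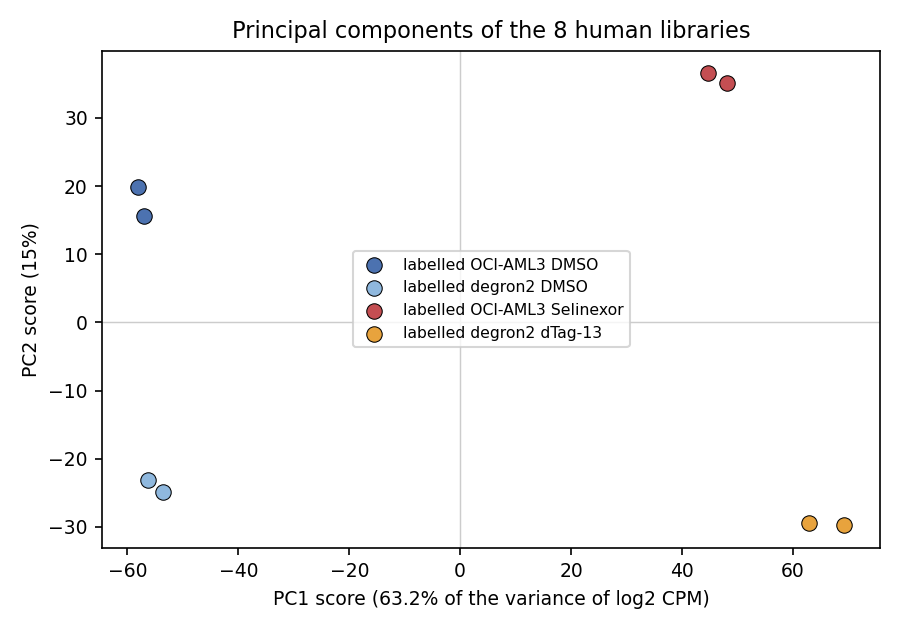
Principal component scores of the 8 human libraries from log2 CPM, coloured by labelled group (2 libraries each). The first component, with 63.2% of the variance, parts the 4 libraries labelled DMSO (scores -58.13 to -53.64) from the 4 labelled treated (44.66 to 69.27), and the second, with 15%, parts the labelled lines.

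Clusters that rose in both labelled treatment comparisons numbered 1496, where 415.7 would be shared by independent lists of these sizes. Those that fell in both numbered 1238, against 340.5, and 73 were called in opposite directions (24 of them higher with labelled dTag-13). The fold changes correlated across the 13590 clusters (Pearson's r = 0.786, Spearman's rho = 0.684). Clusters are not independent replicates, so no p is given. The comparisons share no library. Under the file names, however, both set OCI-AML3 against the degron line, so a line difference would give such an overlap as well as a shared response would. Averaged over both labelled lines, labelled treated libraries differed from labelled DMSO libraries in 6359 clusters, 319 of them past 16-fold, while labelled degron2 differed from labelled OCI-AML3 in 3508, of which 11 were past 16-fold. Without a count in all 4 libraries labelled DMSO but with at least 20 in each of the 4 labelled treated, there were 27 clusters, and 1 showed the opposite. By the same measure 0 clusters were without a count in all 4 libraries of a labelled line and counted in each of the other labelled line, in either direction.

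**Figure D2:**
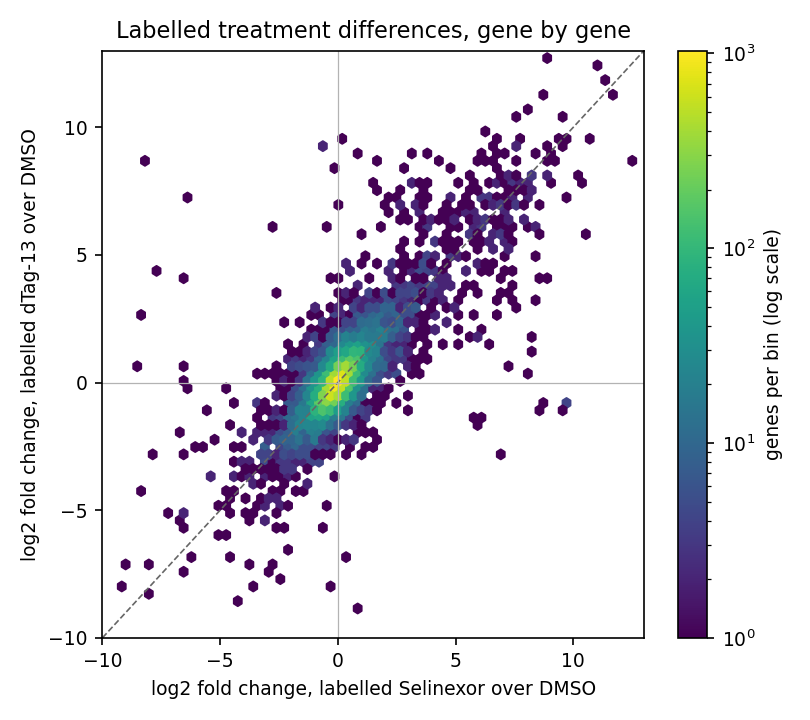
Log2 fold changes of 13590 human gene clusters, labelled Selinexor over DMSO in OCI-AML3 on the x axis and labelled dTag-13 over DMSO in degron2 on the y axis, with colour for the number of clusters per bin and a dashed line of equal change. Most clusters far from 0 lie along the line (r = 0.786 across clusters). Under the file names both axes show OCI-AML3 over the degron line. Extreme values include clusters without a count in a group, whose fitted folds are no bounds.

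The lines were also compared under the same labelled condition. Between the DMSO libraries labelled degron2 and OCI-AML3, 1114 clusters differed, 519 higher and 595 lower in degron2, and none of the 4 clusters named above was among them. With library totals as the only scaling the split was 598 higher and 455 lower. Under the file names this comparison is dTag against DMSO within the degron line. The count was 1898 in a fit of these 4 libraries alone, 327 and 294 without replicate 1 or 2 labelled OCI-AML3 DMSO, and 256 and 373 without replicate 1 or 2 labelled degron2 DMSO. Between the libraries labelled dTag-13 and Selinexor, 3115 clusters differed, 1435 higher and 1680 lower with labelled dTag-13, a split that turned to 1543 higher and 1438 lower with library totals as the only scaling. Cluster 31197 was higher with labelled dTag-13 (log2 fold change 1.19, SE 0.213, adjusted p = 0.00383, edgeR). Under the file names this comparison is KPT against DMSO within OCI-AML3. Of the clusters higher in degron2 under labelled DMSO, 225 were also higher under the labelled treatments (54.8 if independent), and 28 were lower. Of those lower under labelled DMSO, 348 were also lower (73.55 if independent), and 25 were higher. The fold changes of these 2 comparisons correlated with Pearson's r = 0.255 and Spearman's rho = 0.397 across clusters. Under the file names this overlap is the one between the dTag effect in the degron line and the KPT effect in OCI-AML3.

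The labelled dTag-13 and Selinexor effects differed in 538 clusters by the test of their difference, with 240 more positive and 298 more negative for labelled dTag-13. Of these, 146 changed in the same direction in both comparisons and 73 in opposite directions, while 232 were called with labelled dTag-13 alone and 87 with labelled Selinexor alone. Cluster 28722 was among them (difference of log2 fold changes -4.31, SE 0.846, adjusted p = 0.0168, edgeR), a call lost without replicate 1 or 2 labelled Selinexor, without replicate 2 labelled dTag-13 and with DESeq2 (0.0775, 0.0602, 0.0577 and 0.0565). The set of clusters does not depend on which names are right, but the sign does, since the file names turn it into the KPT effect minus the dTag effect. By labels and file names alike, each compound was given to a single line, so compound and line are not separated in this difference. Without single libraries the count was 262 and 187 (labelled OCI-AML3 DMSO replicates 1 and 2), 179 and 309 (degron2 DMSO), and 338 and 307 (Selinexor).

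In the mouse cells the comparison of knock-in clones with the parental line asks what NPM1c changes in progenitors. Npm1, the targeted gene, was lower in the clones, at a normalized read count of 14530 ± 535 (SD, n = 3) against 25700 ± 13.7 (SD, n = 2), a log2 fold change of -0.82 (SE 0.0673, adjusted p = 0.000533, limma). The table has a single value per gene, so mutant and normal transcripts are not separated, and Npm1 reads can be shared with its pseudogenes. Hoxb8, the immortalizing gene, was at 5492 ± 1280 in the clones and 6406 ± 461 in the parental cells, which did not pass the test (adjusted p = 0.438, limma). Reads of an introduced Hoxb8 would not be separated from those of the cells' own gene. Hoxb7 was at 545.5 ± 32.6 and 688.3 ± 4.42 (adjusted p = 0.113, limma). The 11 HOXA genes, which are high in human NPM1c leukaemia, together had 3 of 29020663 reads in the clones and 1 of 109285735 in the parental libraries, so no difference was detectable at this depth. Only 2 HOXB genes, Hoxb7 and Hoxb8, were abundant enough to test. Hoxb4, below the minimum for testing, was at 1.231, 4.755 and 0 in the clones and at 17.09 and 17.10 in the parental libraries.

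Genes of the HOX cofactor and progenitor list moved both ways, with 5 of 21 tested members higher, 5 lower and 11 not passing (5 and 5 also when adjusted over the list alone). The list as a whole did not pass (camera, adjusted p = 0.623), and its mean log2 fold change of -0.36 differed in sign from its median of 0.16 and from the upward direction of the test. Mef2c, a myeloid and lymphoid transcription factor, had no read in the clones against 471.6 ± 84.6 (SD, n = 2) in the parental libraries, at least 303-fold lower against a floor of 3 reads over the group (176-fold without clone 12). Smc4, a condensin subunit, was 3.09-fold lower (log2 -1.63, SE 0.0914). Gata2, which acts in stem cells and mast cells, was 2.61-fold higher (log2 1.38, SE 0.126), and Hlf, a stem cell transcription factor, 1.70-fold higher (log2 0.76, SE 0.114). Meis1, the HOX partner, was at 1700 ± 364 in the clones and 1404 ± 162 in the parental cells (adjusted p = 0.366, limma).

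In the mast cell, basophil and eosinophil list 4 of 6 tested members were higher in the clones and the other 2 did not pass (5 higher when adjusted over the list alone). The median log2 fold change was 2.89 (camera, adjusted p = 1.91e-05, and adjusted p = 0.330 with an estimated correlation). Tpsb2, a mast cell tryptase, was at 216.8 ± 143 (SD, n = 3) in the clones with no read in the parental libraries, at least 520-fold higher, although its reads can be shared with the related Tpsab1. Its clones ranged from 75.91 to 361.4, and the bound was 346 without clone 18 and 46.5 without the deep parental replicate 2. Ms4a2, the beta chain of the high-affinity IgE receptor, rose from 24.19 ± 10.0 to 383.4 ± 179, Il5ra, the interleukin-5 receptor, from 2.762 ± 1.71 to 77.01 ± 3.54, and Mcpt8, a basophil protease, from 178.2 ± 84.1 to 629.6 ± 81.2 (adjusted p = 0.00252, 0.000819 and 0.00744, limma). Cpa3, a mast cell carboxypeptidase, did not pass (3425 ± 857 against 1418 ± 1460, adjusted p = 0.225, limma), and its parental libraries differed widely (2450 and 386.2), so that it passed without parental replicate 1 (0.0016). Hdc, which makes histamine, did not pass either (1732 ± 877 against 752.8 ± 45.1, adjusted p = 0.139) except without clone 18 (0.0339, limma). Parental replicate 2 was more than 1.5 times below replicate 1 in 2 of the 6 tested members. The reverse held in another 2, and each parental library was below every clone in all 6. Of the list's untested genes, Mcpt4, Prg2, Epx and Ccr3 stayed below 2 in all 5 libraries. Cma1 was at 4.924, 19.02 and 0 and Fcer1a at 2.462, 11.1 and 0 in clones 12, 18 and 4, with no parental read, and Tpsab1 was at 6.154 in clone 4 and below 1 elsewhere.

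The largest rises included further receptors and enzymes. Cyp11a1, which makes pregnenolone from cholesterol, was at 393.7 ± 65.6 in the clones with no parental read, at least 944-fold higher, or at least 84.5-fold without the deep parental replicate 2 (log2 8.61, SE 0.283, adjusted p = 3.22e-05, limma). Emx2, a homeobox gene, was at 213.3 ± 94.4, at least 511-fold higher (45.8-fold without parental replicate 2), and its reads may not be separable from those of its antisense partner Emx2os. Il1rl1, the interleukin-33 receptor of mast cells and basophils, was 308-fold higher, Chn2 229-fold and Abca8b 176-fold, on the log2(value + 1) scale. Among the largest falls were cell surface and signalling genes. Grb10, an adaptor of growth factor receptors, had no read in the clones against 470.9 ± 53 in the parental cells, at least 303-fold lower (176-fold without clone 12). Gpr124, a receptor of endothelial Wnt signalling, fell 1290-fold (95% counting interval 232 to 51100), the matrix metalloprotease Mmp14 517-fold (92.7 to 20400) and the cadherin Cdh23 256-fold (87.4 to 1240). The semaphorin receptor Nrp2 went from 785.2 ± 7.35 to 7.056 ± 8.44 (adjusted p = 0.0183), but not past the threshold without clone 18 (adjusted p = 0.0697, limma).

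**Figure D3:**
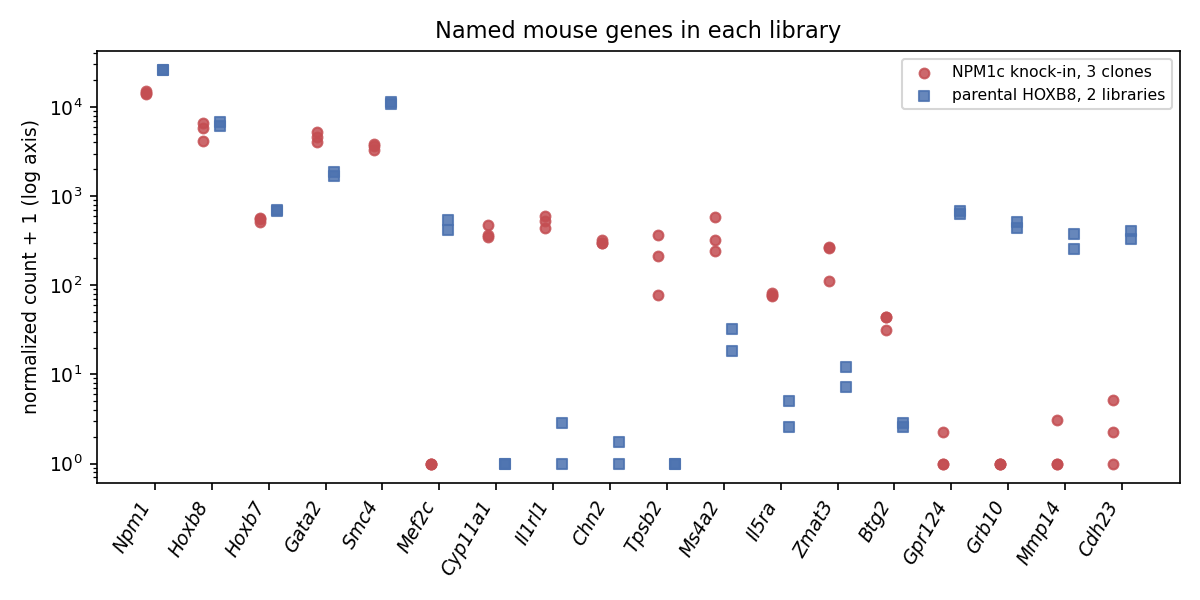
Normalized read count plus 1 (log axis) of named mouse genes in each library, with circles for the 3 knock-in clones and squares for the 2 parental libraries. A point at 1 is a library without a read. Every gene shown except Hoxb8 and Hoxb7 passed the test, and no clone overlaps a parental library in any of those.

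In the G2 and mitosis list 16 of 28 members were lower and 12 did not pass (22 lower when adjusted over the list alone), with a median log2 fold change of -0.63 (camera, adjusted p = 2.48e-09, and adjusted p = 0.330 with an estimated correlation). Ccna2 fell from 3924 ± 284 to 1699 ± 243, Hmmr from 2712 ± 276 to 1495 ± 61.4, Cdk1 from 3477 ± 40.3 to 2179 ± 233 and Tpx2 from 3613 ± 276 to 2363 ± 216. In the DNA replication list 13 of 30 were lower and 17 did not pass (21 lower when adjusted over the list alone), with a median of -0.69 (camera, adjusted p = 7.19e-09, and adjusted p = 0.330 with an estimated correlation). Pola1, the catalytic subunit of DNA polymerase alpha, fell from 930.9 ± 21.6 to 436.5 ± 69.4, with Pole, Rfc3 and Cdc45 1.8-fold, 2.05-fold and 1.87-fold lower. Without parental replicate 2, Tpx2, Pole and Rfc3 did not pass (adjusted p = 0.0647, 0.0503 and 0.0570, limma), nor did Cdc45 without clone 12 or parental replicate 1 (0.0568 and 0.0519). The parental libraries stood apart in some members: replicate 2 was more than 1.5 times below replicate 1 in 4 of the 28 and 5 of the 30, and below every clone in 2 and 3. Mcm3, for example, was at 1813 in replicate 1 and 584.9 in replicate 2, and at 1034 to 1373 in the clones.

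Of 23 cholesterol synthesis genes 13 were lower and 10 did not pass (15 lower when adjusted over the list alone), with a median log2 fold change of -0.53 (camera, adjusted p = 1.16e-06, and adjusted p = 0.330 with an estimated correlation). Lss, which closes the sterol ring, fell from 3494 ± 237 to 1767 ± 189, Idi1 from 6647 ± 98.7 to 3379 ± 559, Tm7sf2 from 1211 ± 20.9 to 683.3 ± 27.1 and Pmvk 2.58-fold. In the glycolysis and hypoxia list 10 of 24 were lower, 2 higher and 12 did not pass (11 lower and 2 higher when adjusted over the list alone), with a median of -0.37 (camera, adjusted p = 1.91e-05, and adjusted p = 0.342 with an estimated correlation). The members with the smallest p were Vegfa, 3.01-fold lower, Ankrd37, 9.11-fold, P4ha1, 2.21-fold, and Bnip3, 3.04-fold. The 2 that rose were the glucose transporter Slc2a3, from 251.5 ± 68.4 to 638.1 ± 161, and the hexokinase Hk1, from 12080 ± 155 to 14460 ± 497. Parental replicate 2 was more than 1.5 times below replicate 1 in 7 of the 23 cholesterol and 4 of the 24 glycolysis and hypoxia genes, Bnip3 among them (1098 and 656.3), and below every clone in 5 and 3.

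In the p53 target list 10 of 21 members were higher, 1 was lower and 10 did not pass (11 and 1 when adjusted over the list alone). The median log2 fold change was 0.46 (camera, adjusted p = 0.000518, and adjusted p = 0.330 with an estimated correlation). Zmat3, an RNA-binding protein, rose from 8.603 ± 3.38 to 214.1 ± 89.5, the antiproliferative Btg2 from 1.693 ± 0.197 to 38.76 ± 7.49, Trp53inp1 from 425.9 ± 23.9 to 1342 ± 368 and the apoptosis effector Bax from 584.2 ± 94.5 to 1280 ± 20. Cdkn1a, the cell cycle inhibitor, was 1.56-fold higher (adjusted p = 0.0275, limma), a call lost without clone 12 or 4 or parental replicate 2 (0.0950, 0.0518 and 0.123) and without the low-value filter (0.0570). Mdm2 did not pass (1787 ± 367 against 1582 ± 114).

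**Figure D4:**
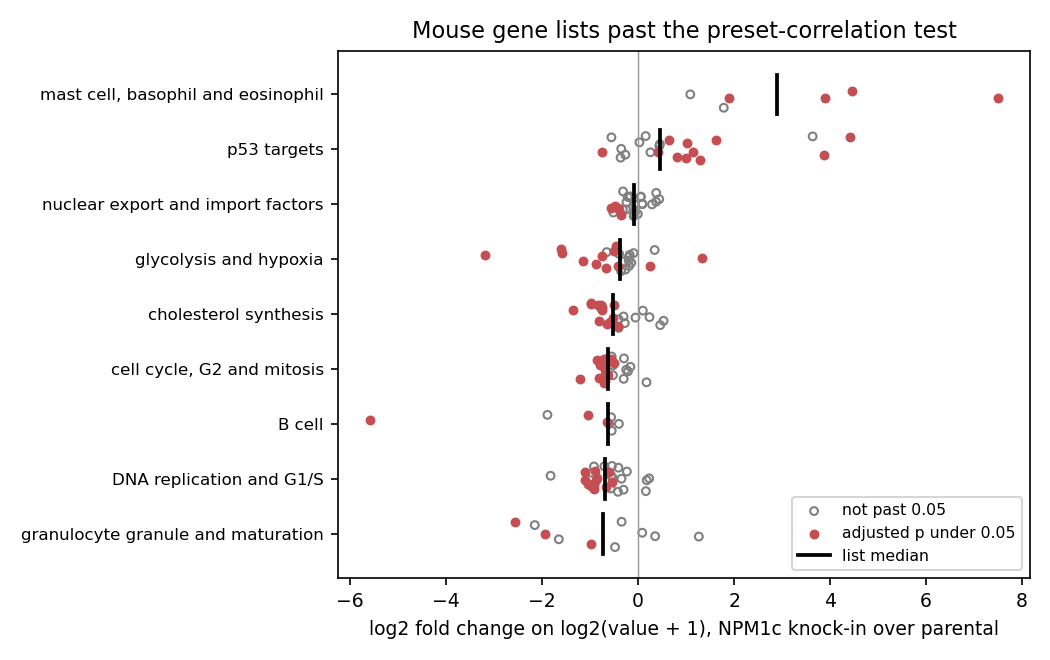
Log2 fold changes, knock-in over parental, of the tested members of the 9 mouse gene lists past an adjusted camera p of 0.05 with the preset correlation. Filled points are members past an adjusted p of 0.05, open points are the others, and bars are list medians, from -0.73 (granulocyte list) to 2.89 (mast cell, basophil and eosinophil list). None of the 9 passed with an estimated correlation.

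Of 10 granulocyte genes 3 were lower and 7 did not pass (5 lower when adjusted over the list alone, camera, adjusted p = 0.0423, and adjusted p = 0.330 with an estimated correlation). Csf3r, the G-CSF receptor, was 3.80-fold lower, Elane, neutrophil elastase, 5.92-fold and Prtn3 1.97-fold, while Ncf1 (4056 ± 376 against 5128 ± 126) and Mpo (13910 ± 6070 against 40740 ± 3010) did not pass (adjusted p = 0.0535 and 0.0629, limma). The list did not pass without parental replicate 1 (0.156). The Elane call was lost without clone 12, clone 4 or parental replicate 1 (0.0791, 0.113 and 0.0979), and the Prtn3 call without any of these or parental replicate 2 (0.103, 0.0975, 0.0979 and 0.0955). Without clone 4, Ncf1 and Mpo passed (0.0144 and 0.0340), and Mpo also without clone 18 (0.0292). With DESeq2 on recovered reads Ncf1 and Mpo both passed (0.0255 and 0.00857), and Ncf1 also passed with edgeR and TMM on recovered reads (0.0494) and with parental replicate 2 thinned to the reads of replicate 1 (0.0486). Without the low-value filter the list, Elane and Prtn3 did not pass (0.0959, 0.0638 and 0.0638). Parental replicate 2 was more than 1.5 times below replicate 1 in 3 of the 10 genes.

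Of 8 B cell entries 3 were lower and 5 did not pass (3 lower when adjusted over the list alone, camera, adjusted p = 0.00428, and adjusted p = 0.330 with an estimated correlation). Cd79b, a B cell receptor component, had 2 reads in the clones, 86.3 times below the parental level (95% counting interval 23.8 to 714), and Igll1, of the pre-B cell receptor, fell from 3668 ± 235 to 1792 ± 377. Ebf1, a B lineage factor, was 1.57-fold lower, while Rag1 (25.16 ± 1.72 against 37.26 ± 2.15) did not pass (adjusted p = 0.239, limma). Calls were lost for Cd79b without parental replicate 2 (0.0573) and for Ebf1 without clone 18, parental replicate 1 or parental replicate 2 (0.0548, 0.0644 and 0.102) or the low-value filter (0.0656). Here parental replicate 1 was more than 1.5 times below replicate 2 in 3 of the 8 entries. Of 27 nuclear export and import factors 4 were lower and 23 did not pass (4 lower when adjusted over the list alone, camera, adjusted p = 0.0220, and adjusted p = 0.330 with an estimated correlation). Xpo1, the export receptor, fell from 7688 ± 603 to 5495 ± 256, with Cse1l, Kpna2 and Nup88 1.49-fold, 1.33-fold and 1.28-fold lower. Without parental replicate 2, Xpo1, Kpna2 and Nup88 did not pass (0.0737, 0.0952 and 0.186), nor did Kpna2 without clone 12 (0.0511) or Nup88 without clone 12, clone 4 or parental replicate 1 (0.129, 0.0503 and 0.0546) or the low-value filter (0.0604). The list did not pass without parental replicate 1 (0.294) or with edgeR on recovered reads (0.0984). Parental replicate 2 was more than 1.5 times below replicate 1 in 6 of the 27 and below every clone in 8.

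Over all genes, 2101 of 13132 changed by limma (adjusted p under 0.05), with 986 higher and 1115 lower in the clones. At least 2-fold changes numbered 479 upward and 386 downward, and at least 16-fold changes 72 and 73. In each of the 2101 genes all clones lay on the same side of both parental libraries. Of the tested genes, 6597 (50.2%) showed this separation, against 20% by chance if the 5 libraries were exchangeable. The parental pair may differ only technically, so 20% may be too low a benchmark. The count was 990 without parental replicate 2, the library of deviating depth, and 1023 without clone 12. The majority of lower genes turned without either parental library, to 1230 higher and 576 lower without replicate 1, where 1191 of the 2101 calls were kept, and to 590 higher and 400 lower without replicate 2, where 907 were kept. All clones were derived from single cells and no label gives a cloned parental control, so cloning and knock-in are not separated by the design.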

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

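The tests of gene length and of clusters without a count were chosen after the results were seen, while the test of the difference between the effects was planned. The difference between the labelled dTag-13 and Selinexor effects was singled out because the test of the difference itself passed in 538 clusters, although the effects correlated over all clusters.

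The largest human differences part the libraries labelled DMSO from those labelled dTag-13 or Selinexor, in both labelled lines alike. The tables argue against a gene length trend as the whole cause, since 90.8% or more of the calls of each labelled treatment comparison stayed past the threshold with the trend removed. Fragment length, which was longer in the labelled treated libraries of each labelled line, was not tested as a cause. What also stays open is whether the files sit at the wrong sample records. Under the file names the same split is OCI-AML3 against the degron line, and 27 clusters without any count in the 4 libraries labelled DMSO but counted in all 4 labelled treated could come from a line difference as well as from the treatments, so these cannot be told apart. By the same measure 0 clusters followed the labelled line in either direction. The outcome set for files at the right records, clusters along the labelled line and none along the labelled treatment, was therefore not met. Past 16-fold, 319 clusters followed the labelled treatment and 11 the labelled line. These counts go with the file names, but treatments that switch clusters on would give them too, so they do not decide. The planned reading of FKBP1A, XPO1 and the HOX genes could not be run without cluster names. If the labels hold, a shared response to losing NPM1c and to blocking XPO1 remains as the untested biological explanation of this split. Under the file names such a response would lie in the comparisons of the labelled lines instead. Those shared 225 clusters upward and 348 downward (54.8 and 73.55 if independent).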

How the results depend on the processing

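Added after the data were seen were the mouse filter at 50, edgeR with TMM on recovered reads and the thinning. Of 83 alternative counts of changed genes, 64 stayed within 1.5 times the reported count. The 4 named human clusters kept their direction and call for both labelled treatments in each of 14 alternatives, as did cluster 31197 for labelled dTag-13 against Selinexor (adjusted p up to 0.0341). The call of cluster 28722 was lost in 4 of 13 for the difference of effects and in 2 of 13 for labelled dTag-13 against Selinexor. DESeq2 was among the losses of both (adjusted p = 0.0565 and 0.0545). Of 62 called mouse genes 48 kept their call. In the other 14, the call was lost in 33 fits, while 9 values of genes not called passed. Among the 987 alternative values of mouse genes, no direction turned where the gene was called in the reported or the alternative fit. Turns of genes called in neither fit were not counted. Nothing in the labels says that equal replicate numbers share a culture, and the correlations of replicate differences were -0.0643 for labelled OCI-AML3 DMSO with Selinexor, -0.0565 for degron2 DMSO with dTag-13 and 0.159 for the pair of DMSO groups. The reported tests are therefore unpaired, and a replicate block gave 704 clusters for labelled degron2 DMSO against OCI-AML3 DMSO and 300 for the difference of effects, within 1.5 times for the rest. A fit of 4 libraries gave 1898 for labelled degron2 DMSO against OCI-AML3 DMSO. Leaving out each library gave 3576 to 5686 (labelled dTag-13), 2105 to 4048 (Selinexor), 256 to 1353 (degron2 DMSO against OCI-AML3 DMSO), 2087 to 2773 (dTag-13 against Selinexor), 179 to 561 (difference of effects) and 990 to 2115 (mouse). Where a group was left with a single library, it was assumed to vary like the others. Fewer libraries entered these fits, and no further cause was tested. In the mouse, the thinning left 2033 genes, edgeR on recovered reads called 2265 genes and DESeq2 2677. With an estimated correlation all 9 list calls were lost (camera, adjusted p = 0.330 to 0.342). The estimated correlation was 0.00963 for B cells and -0.00713 for nuclear transport, not above the preset of 0.01. For these lists a higher correlation between members therefore did not cause the loss, and this form of the test is stricter for other reasons as well. The other called lists were above the preset, at 0.049 (granulocytes), 0.0906 (mast cells), 0.215 (p53) and 0.311 (cholesterol). Glycolysis was at 0.43, DNA replication at 0.52 and G2 and mitosis at 0.569. There a higher correlation may have added to the loss, and p-values with the preset may be too small. With the preset correlation the highest adjusted p over the alternatives was 5.18e-06 for G2 and mitosis, 2.01e-05 for DNA replication, 0.000302 for mast cells, 0.00105 for cholesterol, 0.00421 for glycolysis, 0.00467 for p53, 0.0291 for B cells, 0.156 for granulocytes and 0.294 for nuclear transport. At the real depths and replicate numbers, 14.3% (human) and 16.4% (mouse) of simulated changes of 0.5 on the log2 scale were recovered.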

Other observations

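The genes named here were chosen after their values were seen, as were the thinning and the counts per clone. The list tests were planned. The mouse lists given here did not pass as a whole or had fewer than 5 tested members, which were too few for a list test. Itga2b, the platelet and progenitor integrin, was 10.2-fold higher in the knock-in clones (2161 ± 461, SD, n = 3, against 209.3 ± 19.1, SD, n = 2), in a megakaryocyte list with 1 of 6 higher and 1 lower (2 and 1 when adjusted over the list alone, camera, adjusted p = 0.460). The MHC class II gene H2-Ab1 rose 5.37-fold in a list with 3 of 5 higher and 1 lower (the same numbers when adjusted over the list alone). The list's adjusted p was 0.362 by camera, and 0.180 to 0.625 over the alternatives that left at least 5 members. Hbb-b1, a beta globin whose reads can be shared with Hbb-b2, had 46.07 ± 18.7 against 0.3817 ± 0.540, in an erythroid list with 2 of 3 tested members higher (2 higher and 1 lower when adjusted over the list alone). Pecam1 was 2.44-fold higher and was the single call among 3 stromal and endothelial genes. For the stromal and dendritic lists the counts adjusted over the list alone were the same. In the monocyte list, with 2 of 15 higher and 2 lower (2 and 2 when adjusted over the list alone, camera, adjusted p = 0.623), Emr1 was 4.01-fold higher, and Klf4 fell from 37.55 ± 8.42 to a single read (ratio 63.1, 95% counting interval 11.2 to 2500), a call lost without parental replicate 2 (adjusted p = 0.124, limma). Of 3 tested dendritic genes 1 was higher and 2 lower, with a median log2 fold change of -0.46 and a mean of 0.27 that differed in sign, and the 2 tested T and NK cell genes, Lck and Nkg7, did not pass.

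Interferon-stimulated genes had 5 of 24 lower and 1 higher (5 and 1 when adjusted over the list alone, camera, adjusted p = 0.0909, but 0.0310 without the filter and 0.0310 to 0.352 over all alternatives), among them Ifih1, 2.46-fold lower. Of 21 immediate early genes only Icam1 was called, 2.90-fold higher (1 also when adjusted over the list alone, camera, adjusted p = 0.0661). That list passed without the filter, without clone 12 and without clone 18 (0.0273, 0.0489 and 0.0417), within a range of 0.0273 to 0.330 over all alternatives. Of 27 stress genes 4 were higher and 1 lower (4 and 1 when adjusted over the list alone, adjusted p = 0.623, camera), and of 32 MYC and ribosome biogenesis genes 1 was lower, which did not pass when adjusted over the list alone (adjusted p = 0.623, camera). Outside the lists, Cdkn2a, which encodes p16 and p19, was at 1429 ± 220 in the clones against 41.59 ± 10.5 (log2 5.08, SE 0.209, adjusted p = 4.87e-05, limma). The cell cycle gene Ccnd1 was 48.2-fold higher, the lipoxygenase Alox5 61.8-fold and the mast cell and basophil receptor Cd200r3 30.5-fold, each higher in 3 of 3 clones.

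The mouse calls rest on a parental pair of which replicate 2 has 99557475 reads and replicate 1 has 9728260. Thinned at random to the reads of replicate 1, replicate 2 left 92.9% of the calls in place (1952 of 2101), which argues against its depth as their whole cause. Whether that library also differs in preparation is not given by the labels. No biological explanation was tested.

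In the knock-in clones 4 of 6 mast cell, basophil and eosinophil genes were called higher and 16 of 28 G2 and mitosis genes lower, and neither list passed with an estimated correlation (adjusted p = 0.330). With the preset correlation, the larger adjusted p of the list tests after the same thinning was 2.35e-05, which argues against read depth, though not against other differences between the parental libraries. Each of the 3 clones had all 6 of the tested mast cell, basophil and eosinophil genes above both parental libraries, and 24, 23 and 26 of the 28 G2 and mitosis genes were below both in clones 12, 18 and 4. Clone 4 stood apart on the second principal component (-49.61, against 19.47 and 28.82 for clones 12 and 18, with 17.9% of the variance). A change common to single-cell clones, such as outgrowth of a cell type during cloning, cannot be told apart from an effect of NPM1c, because no cloned parental line is among the labelled groups. An effect of NPM1c remains as an untested biological hypothesis.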
